A study of Caenorhabditis elegans with 4 samples.

How the data were processed

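RNA was measured in Caenorhabditis elegans L2/L3 larvae, grown from starved L1 larvae for 24 h at 22 °C and kept for 2 h on 1 mM auxin (indole-3-acetic acid). Poly(A)-selected RNA, extracted with Trizol after freeze-cracking, was made into stranded dUTP libraries, per the labels' protocols. The 4 samples form 2 groups of 2 libraries each, and each group was compared by the authors with the strain CA1200 after 2 h on auxin. The control libraries are not among the 4 samples and are not analysed here as samples. The series' design text speaks of biological replicates without saying more about separate cultures. The authors' p-values therefore measure only the spread between the libraries of each comparison, those of the control included.

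The values come from 2 result tables that the authors deposited, with a line per gene and no value per sample. Mean normalized counts, a signal that is never negative, were deposited by the authors as the mean over the libraries of a comparison. The log2 fold changes of depletion over control and their standard errors (SE) were deposited by the authors and show no sign of shrinkage. The score is the Wald statistic of that fold change, as deposited, and each p-value and adjusted p-value is the authors' own, per the file headers. The column names are those of DESeq2, and the submitters' processing notes name DESeq2 1.30.0, which the authors used for these deposited values. The same submitters' processing notes name CASAVA 1.8, HISAT2 2.2.1, HTSeq 0.13.5 and Cufflinks 2.2.1, without saying what each was used for. The genome build is not given in the sources used here, so no coordinates are printed, and chromosomes are those of the authors' deposited tables. Whether counting used strand, and how reads that match several genes were treated, is not given in the sources used here, so members of near-identical families (histones, small heat shock proteins, collagens, glutathione S-transferase clusters) are uncertain one by one.

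The table of the TOP-2 and DPY-27 depletion has 16927 genes and that of the TOP-1 and DPY-27 depletion 17187, with 16623 in both. An adjusted p was missing for 1969 and 2333 genes, and these stayed missing. Of the 17491 gene names in either table, 98.06% matched a gene model of Ensembl release 115 (WBcel235), which was used for gene span, exonic length, biotype and symbols only. Total reads per library are unknown from these tables. The mean normalized counts sum to 15781972 and 15729010, and the median SE of a log2 fold change is 0.413 and 0.397, which sets the precision. How many libraries show the direction of a change cannot be told without values per sample.

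Genes were called at an adjusted p under 0.05 from the authors' DESeq2 test, and adjusted p-values of single genes below are all of that kind. The X shift is the median log2 fold change of X genes minus that of genes on chromosomes I to V, over genes with a mean normalized count of at least 10. It was set against 10000 random gene lists of equal size matched on 10 strata of mean expression. Fisher's exact test, two-sided, compared the share of X and autosomal genes called. Relations of fold change with gene span (start to end) were given as Spearman and Pearson correlations over protein-coding genes, with 100000 permutations, and adjusted by Benjamini-Hochberg over the 4 relations. The smallest p that the random lists can give is 0.0002, and the smallest the permutations can give is 1e-05. Genes are not independent replicates, so p-values across genes describe these tables and not a population of animals.

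The difference between the depletions was taken per gene as the log2 fold change after TOP-2 and DPY-27 depletion minus that after TOP-1 and DPY-27 depletion, in which the common control cancels. Its SE came from both deposited SEs taken as independent, which overstates it, with a Wald z and Benjamini-Hochberg adjustment over 13027 genes. Overlap between the depletions was set beside independent lists and beside 100 simulations of unchanged groups against a common control.

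Fixed before the data were examined were 34 gene lists: condensin DC and its recruiters, condensin I and II, cohesin and its regulators, topoisomerases, X signal elements and xol-1, histone genes, heat shock response, endoplasmic reticulum (ER) and mitochondrial unfolded protein responses, DNA damage response and repair, cytochrome P450s, UDP-glucuronosyltransferases, glutathione S-transferases, innate immune effectors, pals genes, cuticle collagens, moulting genes, hedgehog-related genes, germline, sperm genes, vitellogenins, body wall muscle, pharynx, intestine, neurons, neuropeptides, hypodermis, ribosomal proteins, RNA polymerase I and ribosome biogenesis, DNA replication and mitosis, nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, ribosomal RNA genes and fatty acid metabolism. The 31 lists with 3 or more measured members (mean normalized count of at least 10) were tested by the place of their median among 10000 random lists matched on expression, with Benjamini-Hochberg adjustment over all lists and both depletions, and the p of a list below is that adjusted p. In the difference between the depletions, where cameraPR on the difference over its SE was added after seeing the data, the adjustment ran over its own 31 lists. Condensin DC and condensin I and II hold 4 genes in common, and innate immune effectors and neuropeptides 3. As an alternative, limma's cameraPR ran on the deposited score with preset correlations of 0.01 and 0.05. A camera test with an estimated correlation needs values per sample and was not possible.

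Genes were named by a rule fixed before the data were examined. Among genes with an adjusted p under 0.05 and a mean normalized count of at least 50 it takes the 10 largest positive and the 10 largest negative fold changes of each table, and the 5 X genes with the smallest p among those higher. It also takes top-1, top-2, dpy-27 and all members of the condensin DC list, and up to 4 called members of each list by smallest p. For the difference it takes up to 5 called genes in each direction with a mean of at least 50 in both tables. Genes without a gene symbol of their own were skipped by the rule. Any other gene is said to have been chosen after its values were seen.

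Alternatives were other thresholds, floors on mean expression, adjustments, summaries, matching on gene span, and leaving out gene groups or chromosomes. Leaving out replicates, a replicate block and splitting the control were not possible without values per sample. The procedures were tested on simulated data made from the deposited means and SEs. For the calls against the control, 50 genes were changed by each size and all others left unchanged. Far more genes were called in the deposited tables, which makes the adjustment there less strict. The recovery given here may therefore be too low for them. Calls recovered 10%, 74%, 94% and 94% of genes changed by 1, 2, 3 and 4 on the log2 scale for the TOP-2 and DPY-27 depletion, over 13203 genes. For the TOP-1 and DPY-27 depletion they recovered 18%, 68%, 86% and 94% over 13283 genes. The test of the difference recovered 0%, 54%, 68% and 88% over 13027 genes. Work was done with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.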

Results

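Transcript levels were measured by RNA sequencing in C. elegans larvae in which a topoisomerase and DPY-27 were removed together. In the auxin-inducible degron system a tagged protein is destroyed once auxin is given to animals that make the plant F-box protein TIR1. In strain AM11 the tag was on TOP-2, the topoisomerase II that passes a DNA duplex through a cut in another, and on DPY-27. In strain AM12 it was on TOP-1, the topoisomerase I that relaxes supercoils by cutting a single strand, and on DPY-27. DPY-27 is the subunit special to condensin DC, the complex that binds both X chromosomes of hermaphrodites and lowers their expression (dosage compensation). Each group had 2 libraries, and the authors compared both with the same control strain, CA1200, after 2 h on auxin. The study's title concerns the part that topoisomerases play in the movement of condensin DC along the X. The comparisons below ask how transcripts from the X and elsewhere differed from the control after each depletion, and whether the depletions differed from each other. Total reads per library are unknown from the authors' deposited tables, and the mean normalized counts sum to 15781972 for the TOP-2 and DPY-27 depletion and 15729010 for the TOP-1 and DPY-27 depletion.

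The transcripts of the tagged genes were measured first. In the authors' deposited table for the TOP-2 and DPY-27 depletion, top-2 (K12D12.1) was at -0.17 ± 0.36 (log2 fold change ± SE, adjusted p 0.798) and dpy-27 (R13G10.1) at -0.13 ± 0.41 (adjusted p 0.873). For the TOP-1 and DPY-27 depletion the authors' deposited table gave top-1 (M01E5.5) at -0.17 ± 0.32 (adjusted p 0.745) and dpy-27 at -0.55 ± 0.37 (adjusted p 0.282). None passed the test. The degron removes protein and not transcript, so these values do not check the labels.

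After depletion of TOP-2 and DPY-27, X-linked genes stood above autosomal genes, by 0.67 on the log2 scale (1.59-fold) at the median. Genes of the pharynx, the feeding organ, had the highest median of the 31 lists tested, among them myo-2 and myo-1, its myosin heavy chains, at a list median of 5.41, followed by genes of the germline at 3.34. A common control that held less RNA of some tissues could also give such medians, as taken up under other observations. Cuticle collagens, histone genes, cytochrome P450s and glutathione S-transferases lay below matched random lists, but none of these 4 calls held in limma's cameraPR with a preset correlation of 0.05 (adjusted p 0.154, 0.291, 0.257 and 0.288), and at 0.01 those of histone genes (0.0774) and glutathione S-transferases (0.0624) were lost. In all, 3223 of 14958 genes differed from the control at an adjusted p under 0.05 in the authors' deposited table, 2105 higher and 1118 lower, so that 65.3% of the calls were higher.

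The X shift after TOP-2 and DPY-27 depletion compares 2096 X genes, with a median log2 fold change of 0.54, with 11107 autosomal genes, with a median of -0.13. Random lists of the same size gave shifts between -0.08 and 0.08 (p 0.0002, the smallest the random lists can give). Of the X genes 78.3% lay above 0, against 42.5% of autosomal genes. Medians of the autosomes ran from -0.15 on chromosome II to -0.12 on chromosome I. Of 2330 X genes tested, 571 (24.5%) rose, against 1534 of 12628 autosomal genes (Fisher's exact test, odds ratio 2.35, p 2.26e-49). Only 53 X genes fell, 2.27%, against 8.43% of autosomal genes (Fisher's exact test, odds ratio 0.253, p 8.7e-32). Along the X the medians of 9 windows of 2 Mb lay between 0.48 and 0.63, above all 43 autosomal windows, which lay between -0.45 and -0.01. Without genes at an absolute log2 fold change of at least 1 in the table of the other depletion, an alternative chosen after seeing the data, the X shift was 0.43. The fold changes of both tables share the control and correlate (Pearson's r 0.91), so this filter by itself tends to lower the shift. Genes are not independent replicates, so these p-values describe the table.

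Among called genes with a symbol and a mean of at least 50, the 10 largest rises in the authors' deposited table for the TOP-2 and DPY-27 depletion were all on the X, and with genes lacking a symbol included 9 of 10 were. They were led by nspc-13 (F42F12.6) at 8.23 ± 0.95 and idpp-9 at 7.81 ± 1.20, followed by aaim-1, abf-5 (a defensin-like antibacterial factor), lron-1, myo-2, fipr-3, idpp-3, clik-2 and phat-6 down to 6.52. The 5 X genes of that kind with the smallest p in the authors' deposited table were myo-2 at 6.83 ± 0.36, clik-2 (calponin-like) at 6.57 ± 0.37, abu-10 (a protein of the pharyngeal cuticle) at 6.49 ± 0.49, pgp-14 (an ABC transporter of the pharynx) at 5.40 ± 0.34 and nlp-49 (a neuropeptide) at 4.99 ± 0.34. The pharynx list as a whole was at 5.41 in these libraries. Of the 10 largest falls chosen in the same way none lay on the X. The authors' deposited table had dhs-23 (a short-chain dehydrogenase) at -6.92 ± 0.67, gba-2 (a glucocerebrosidase) at -6.07 ± 0.65, far-3 (a fatty acid and retinol binding protein) at -5.72 ± 0.51 and cyp-35C1 (a cytochrome P450) at -5.37 ± 0.55. Also among them were hsp-16.2 and hsp-16.41 (small heat shock proteins), mtl-1 (a metallothionein), uroc-1 and the collagens col-133 and col-131, between -4.81 and -4.18 in the authors' deposited table.

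No member of the condensin DC list passed the test after TOP-2 and DPY-27 depletion (0 of 10 adjusted over the list alone, list median 0.23, adjusted p 0.155). In the authors' deposited table its other subunit genes were at 0.25 ± 0.34 (dpy-26), 0.22 ± 0.45 (dpy-28), 0.39 ± 0.35 (mix-1) and 0.19 ± 0.36 (capg-1). The genes of its recruiters stood in the authors' deposited table at 0.52 ± 0.39 (sdc-1), 0.71 ± 0.37 (sdc-2), 0.84 ± 0.42 (sdc-3) and -0.44 ± 0.32 (dpy-30), and dpy-21, also in the list, at -0.00 ± 0.38. Of 8 genes of condensin I and II, 3 rose and 5 did not pass (3 adjusted over the list alone, list median 0.34, adjusted p 0.152), namely hcp-6, capg-2 and smc-4, at 1.33 ± 0.40, 1.15 ± 0.36 and 1.12 ± 0.42 in the authors' deposited table. Of 10 cohesin genes 4 rose and 6 did not pass (4 adjusted over the list alone, list median 0.61, adjusted p 0.104). These were scc-1 and the meiotic subunits coh-4, rec-8, at 4.69 ± 0.58, and coh-3, at 4.72 ± 0.76 in the authors' deposited table. The germline list was at 3.34 in the same libraries. Of 4 topoisomerase genes only cin-4, related to topoisomerase II, rose, by 3.50 ± 0.87 in the authors' deposited table (1 adjusted over the list alone, list median 0.10, adjusted p 0.794). None of the 3 measured X signal elements passed the test (0 adjusted over the list alone, median 0.39, adjusted p 0.616).

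Germline genes rose after TOP-2 and DPY-27 depletion in 23 of 31 cases, 8 not passing and none falling (26 adjusted over the list alone, adjusted p 0.000886). In the authors' deposited table pgl-1 and glh-1, which build the germ granules, were at 4.38 ± 0.43 and 3.86 ± 0.42, and gld-1, a repressor of translation, at 4.36 ± 0.52. Genes of DNA replication and mitosis rose in 14 of 25 cases, with 11 not passing (20 adjusted over the list alone, median 1.00, adjusted p 0.000886, but 0.0534 by cameraPR at 0.05). Examples from the authors' deposited table are mcm-7, of the replicative helicase, at 1.33 ± 0.35, orc-1, of the origin recognition complex, at 1.42 ± 0.39, and the B cyclin gene cyb-2.2 at 3.50 ± 0.94. Of 22 DNA damage and repair genes 6 rose and 16 did not pass (10 adjusted over the list alone, median 0.75, adjusted p 0.00558, but 0.071 by cameraPR with a preset correlation of 0.01), including cep-1, the p53 relative, at 1.72 ± 0.47, chk-2, a meiotic checkpoint kinase, at 2.42 ± 0.71, and the caspase gene ced-3 at 1.28 ± 0.43 in the authors' deposited table. With the germline list at 3.34 in the same libraries, how far germline RNA lies behind the replication and repair lists was not tested. Of 17 genes of RNA polymerase I and ribosome biogenesis 6 rose and 11 did not pass (7 adjusted over the list alone, median 0.61, adjusted p 0.000886, but 0.154 by cameraPR at 0.05), with nucl-1, the nucleolin, at 1.48 ± 0.30 in the authors' deposited table. Histone genes were lower as a list (median -0.80, adjusted p 0.000886, but 0.0774 by cameraPR at 0.01), although only 2 of 29 fell, his-35 and his-72, while his-74 rose, by 3.22 ± 0.40 in the authors' deposited table, and 26 did not pass (1 higher and 0 lower adjusted over the list alone). The libraries were poly(A)-selected, so these values cover only the histone transcripts that the selection caught. Sperm genes had 1 of 8 higher, spe-44, and 7 not passing (1 adjusted over the list alone, median 0.24, adjusted p 0.961).

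Among tissues, 12 of 13 pharynx genes rose after TOP-2 and DPY-27 depletion and 1 did not pass (12 adjusted over the list alone, adjusted p 0.000886), with myo-2, myo-1, myo-5 and tni-4 (troponin I) between 5.41 and 6.83 in the authors' deposited table. Of 19 body wall muscle genes 2 rose, unc-89 and unc-22, giant proteins of the sarcomere, at 1.32 ± 0.46 and 1.45 ± 0.55 in the authors' deposited table, and 17 did not pass (0 adjusted over the list alone, median 0.23, adjusted p 0.0268). The 8 members on the X weigh in this call, since the autosomal members alone had a median of 0.10 and the adjusted p was 0.0682 once the X or autosomal median was subtracted. Of 17 intestine genes 3 rose, including the peptide transporter gene pept-1 at 3.34 ± 0.46 in the authors' deposited table, pgp-1 fell and 13 did not pass (4 higher and 1 lower adjusted over the list alone, median 0.23, adjusted p 0.0868). Neuropeptide genes changed in both directions, 43 of 96 higher, 26 lower and 27 not passing (44 and 30 adjusted over the list alone, median 0.29, adjusted p 0.000886). Over genes with a mean of at least 100 the list no longer passed (adjusted p 0.66), nor did it by cameraPR at 0.05 (0.327). The 31 members on the X weigh in that median, and the autosomal members alone had a median of -0.20. Among them flp-17 was in the authors' deposited table at 5.68 ± 0.51, nlp-71 at 5.48 ± 0.44 and flp-1 at 5.14 ± 0.36. Neuron genes had 5 of 24 higher, 7 lower and 12 not passing (5 and 8 adjusted over the list alone, adjusted p 0.274), with a median of -0.35 and a mean of 0.02. The monoamine transporter gene cat-1 was at 4.26 ± 0.52 in the authors' deposited table, and the touch neuron tubulin genes mec-12 and mec-7 at -2.23 ± 0.35 and -2.03 ± 0.37. Markers of anterior cells outside the pharynx, a list written after the pharynx result but before their own values were seen, had a median of 5.49 with 6 of 7 higher. Posterior markers written in the same way had a median of -1.71 with 5 of 6 lower. Of 13 anterior markers found only those 7 had a mean of at least 10. That floor keeps genes very low in the control only where they are high after the depletion.

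Lists of the cuticle and its renewal had medians below matched random lists after TOP-2 and DPY-27 depletion, but these calls depended on the test. By cameraPR at 0.01 the adjusted p was 0.0774 for moulting and 0.223 for hedgehog-related genes, and at 0.05 it was 0.154 for collagens. Whether these larvae stood at another phase of the moulting cycle than the control was not tested. Cuticle collagens had 26 of 117 lower, 13 higher and 78 not passing (30 lower and 15 higher adjusted over the list alone, median -0.89, adjusted p 0.000886), with col-38 at -4.14 ± 0.49 and col-118 at -2.93 ± 0.37 in the authors' deposited table. Moulting genes had a median of -0.76 (adjusted p 0.00232), with 1 of 24 lower, the transcription factor gene blmp-1, 1 higher, the astacin protease gene nas-6, and 22 not passing (1 and 1 adjusted over the list alone). Hedgehog-related genes had 6 of 40 lower, 4 higher and 30 not passing (6 and 4 adjusted over the list alone, median -0.50, adjusted p 0.00558), with grd-15 at -2.89 ± 0.58 and grl-6 at 3.64 ± 0.57 in the authors' deposited table. Hypodermis genes had 2 of 10 lower, che-14 and lin-26, and 8 not passing (2 adjusted over the list alone, median -0.23, adjusted p 0.684).

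Stress and detoxification genes went apart. Cytochrome P450s fell in 15 of 63 cases and rose in 7, with 41 not passing (15 and 8 adjusted over the list alone, median -0.53, adjusted p 0.000886), with cyp-13B1 at -2.86 ± 0.39 in the authors' deposited table. Glutathione S-transferases fell in 10 of 40 cases and rose in 5, with 25 not passing (11 and 6 adjusted over the list alone, median -0.53, adjusted p 0.00232, but 0.0624 by cameraPR at 0.01), with gst-21 at -3.93 ± 0.42 and gst-41 at 4.71 ± 0.89 in the authors' deposited table. UDP-glucuronosyltransferases had 14 of 62 higher, 12 lower and 36 not passing (15 and 13 adjusted over the list alone, adjusted p 0.794), with a median of -0.02 and a mean of 0.20, among them ugt-57 at 6.33 ± 0.67 and ugt-33 at -4.03 ± 0.50 in the authors' deposited table. Innate immune effectors rose in 7 of 18 cases, with 11 not passing (7 higher and 3 lower adjusted over the list alone, median 0.64, adjusted p 0.00709, but 0.15 by cameraPR at 0.01), including the lysozyme genes ilys-3 and lys-7 at 4.23 ± 0.60 and 3.17 ± 0.55 in the authors' deposited table. Heat shock genes fell in 4 of 11 cases with 7 not passing (5 adjusted over the list alone, median -0.50, adjusted p 0.161), among them hsp-70 at -3.81 ± 0.68 in the authors' deposited table. Of 12 ER unfolded protein response genes only hsp-4, a BiP chaperone, fell, by 1.41 ± 0.39 in the authors' deposited table (1 adjusted over the list alone, median -0.42, adjusted p 0.4). None of 7 mitochondrial unfolded protein response genes passed the test (0 adjusted over the list alone, median 0.08, adjusted p 0.598). Of 18 pals genes 1 rose, pals-23 (0 adjusted over the list alone, median 0.07, adjusted p 0.804). Of 77 ribosomal protein genes rpl-11.1 rose and rpl-12 fell, with 75 not passing (1 higher and 0 lower adjusted over the list alone, median -0.38, adjusted p 0.173). None of 24 oxidative phosphorylation genes passed the test (0 adjusted over the list alone, median -0.30, adjusted p 0.804), and of 15 fatty acid metabolism genes only fat-5, a desaturase gene, fell (1 adjusted over the list alone, median -0.51, adjusted p 0.152). Of the 14 called lists 7 kept an adjusted p under 0.05 in limma's cameraPR with a preset correlation of 0.01. With one of 0.05 only the pharynx and germline lists kept an adjusted p under 0.05, and the lost calls had adjusted p from 0.0534 (DNA replication and mitosis) to 0.693 (body wall muscle).

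The relation of fold changes after TOP-2 and DPY-27 depletion with gene span depended on the processing, and its sign or its call changed under each of the 4 alternatives on autosomes and each of the 4 on the X. As planned, it did not pass the test on autosomes (Spearman rho 0.02 over 10830 genes, permutation p 0.079, adjusted p 0.105), while Pearson's r was -0.05 (permutation p 1e-05, the smallest the permutations can give). On the X rho was -0.01 (permutation p 0.806, adjusted p 0.806) and r was -0.11 (permutation p 1e-05). Autosomal genes over 20 kb had a median of -0.14, with 10 of 170 lower and 9 higher.

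**Figure D1:**
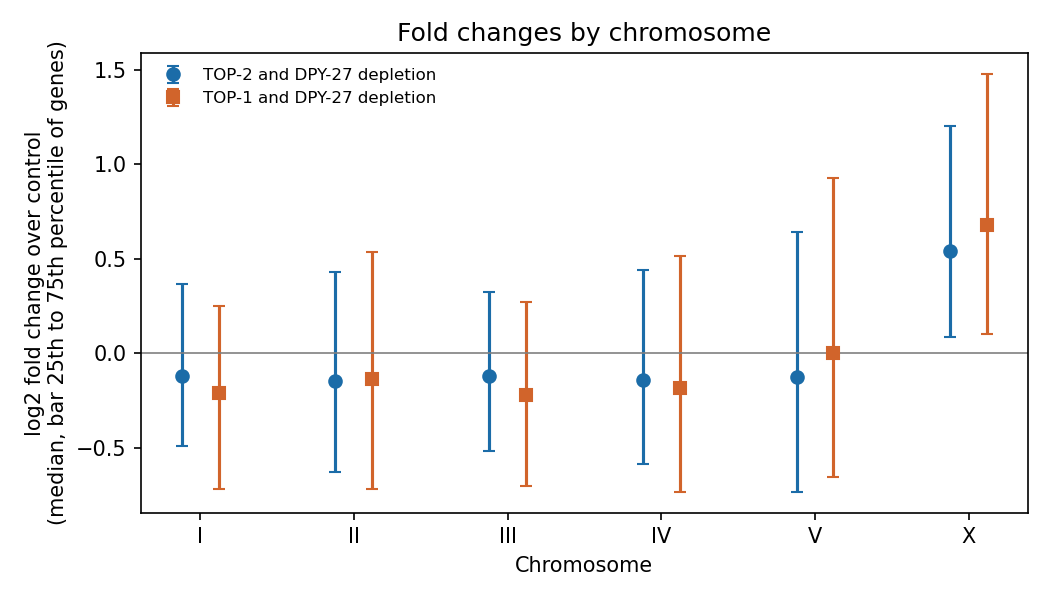
Log2 fold change over control by chromosome for both depletions, with points at the median and bars from the 25th to the 75th percentile of genes. The X medians of 0.54 and 0.68 lie above those of chromosomes I to V, which run from -0.22 to 0.00.

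After depletion of TOP-1 and DPY-27, the X stood above the autosomes by 0.82 on the log2 scale (1.77-fold) at the median. Pharynx genes (list median 4.88) and germline genes (2.93) again had the highest medians of the 31 lists tested. The control was the same, so its content of some tissues may again lie behind these medians. Moulting genes, which drive the renewal of the cuticle, fell in 15 of 24 cases, and long genes stood below short ones on autosomes and on the X. Of 14854 genes, 4442 differed from the control at an adjusted p under 0.05 in the authors' deposited table, 2538 higher and 1904 lower, so that 57.1% of the calls were higher.

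The X shift after TOP-1 and DPY-27 depletion sets a median of 0.68 over 2112 X genes against -0.14 over 11171 autosomal genes, with random lists between -0.08 and 0.06 (p 0.0002, the smallest the random lists can give). Of the X genes 78.6% lay above 0, against 42.2% of autosomal genes. Among autosomes the medians ran from -0.22 on chromosome III to 0.00 on chromosome V. Of 2325 X genes tested 802 (34.5%) rose, against 1736 of 12529 autosomal genes (Fisher's exact test, odds ratio 3.27, p 4.22e-112). A further 83 X genes fell, 3.57%, against 14.5% on autosomes (Fisher's exact test, odds ratio 0.218, p 1.01e-60). Windows of 2 Mb along the X had medians between 0.54 and 0.78, and autosomal windows ran from -0.64 to 0.57, so that the ranges met. Without genes at an absolute log2 fold change of at least 1 in the table of the other depletion, chosen after seeing the data, the X shift was 0.63, and here too the filter by itself tends to lower it.

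Among called genes with a symbol and a mean of at least 50, the largest rises in the authors' deposited table for the TOP-1 and DPY-27 depletion were ifas-2 at 9.01 ± 1.5, dhc-3 (a dynein heavy chain) at 8.18 ± 1.5 and nspc-13 at 8.03 ± 0.94. They were followed by abf-5, clec-42 (a C-type lectin), srlf-37, the collagen gene col-20, phat-6, idpp-9 and pho-8 (an acid phosphatase) down to 7.05, and 4 of the 10 were on the X, as were 4 of 10 with genes lacking a symbol included. Among X genes of that kind the smallest p in the authors' deposited table went to nlp-49 at 5.35 ± 0.34, clik-2 at 6.17 ± 0.39, myo-2 at 6.26 ± 0.40, abf-5 at 7.85 ± 0.55 and cht-1 (a chitinase) at 5.12 ± 0.38. The pharynx list was at 4.88 in these libraries. The largest falls among such genes in the authors' deposited table were dhs-23 at -6.85 ± 0.57, ptr-22 (patched-related) at -6.21 ± 0.48, bus-1 at -5.67 ± 0.61 and uroc-1 at -5.36 ± 0.37. With them went gba-2, col-131, trp-4 (a mechanosensory channel of the TRP family), gst-21, cyp-35C1 and col-133, between -5.12 and -4.16 in the authors' deposited table.

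In the condensin DC list 1 of 10 genes rose and 2 fell after TOP-1 and DPY-27 depletion, with 7 not passing (1 and 2 adjusted over the list alone, median -0.11, adjusted p 0.794). The authors' deposited table had sdc-2, which starts the loading of the complex on the X, at 1.05 ± 0.35 (adjusted p 0.0136), dpy-28, a condensin subunit, at -1.11 ± 0.42 (adjusted p 0.0296) and dpy-21, a histone H4K20 demethylase, at -1.10 ± 0.36 (adjusted p 0.0107). The gene sdc-2 itself lies on the X, whose median was 0.68. The genes of this list are long (median span 7.92 kb), and random lists matched on expression and span were at -0.44. The others were in the authors' deposited table at -0.10 ± 0.33 (dpy-26), -0.13 ± 0.34 (mix-1), -0.10 ± 0.35 (capg-1), 0.42 ± 0.39 (sdc-1), 0.33 ± 0.40 (sdc-3) and -0.22 ± 0.31 (dpy-30). Of 8 condensin I and II genes dpy-28 fell and 7 did not pass (0 adjusted over the list alone, median -0.06, adjusted p 0.775). Of 10 cohesin genes the meiotic rec-8 and coh-3 rose, by 3.94 ± 0.60 and 4.27 ± 0.82 in the authors' deposited table, and 8 did not pass (2 adjusted over the list alone, median 0.14, adjusted p 0.653). The germline list was at 2.93 in the same libraries. Among 4 topoisomerase genes cin-4 rose, by 3.43 ± 0.88 in the authors' deposited table (1 adjusted over the list alone, median -0.01, adjusted p 0.984). Of 3 X signal elements, all on the X, ceh-39 rose, by 1.11 ± 0.44 in the authors' deposited table (1 adjusted over the list alone, median 0.24, adjusted p 0.672).

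Germline genes rose after TOP-1 and DPY-27 depletion in 22 of 31 cases with 9 not passing (23 higher and 1 lower adjusted over the list alone, adjusted p 0.000886), with pgl-1, glh-1, gld-1 and deps-1 between 3.23 and 4.22 in the authors' deposited table. Of 24 DNA replication and mitosis genes 3 rose, cyb-2.2, orc-1 and mcm-7, and 21 did not pass (3 adjusted over the list alone, median 0.57, adjusted p 0.00902, but 0.137 by cameraPR at 0.01). DNA damage and repair genes had 2 of 23 higher, phg-1 and cep-1, and 21 not passing (2 adjusted over the list alone, median 0.49, adjusted p 0.152). With the germline list at 2.93 in these libraries, the part of germline RNA in both lists was again not tested. Of 17 genes of RNA polymerase I and ribosome biogenesis nucl-1 rose, by 0.80 ± 0.30 in the authors' deposited table, and 16 did not pass (0 adjusted over the list alone, median 0.49, adjusted p 0.0124, but 0.381 by cameraPR at 0.01). Histone genes fell in 8 of 29 cases and rose in 2, with 19 not passing (9 and 2 adjusted over the list alone, median -1.09, adjusted p 0.000886). The list no longer passed over genes with a mean of at least 100 (adjusted p 0.26) or by cameraPR (0.0704 at 0.01 and 0.285 at 0.05). In the authors' deposited table his-3 was at -2.01 ± 0.48, his-59 at -1.59 ± 0.48 and his-74 at 2.95 ± 0.44. Here too, poly(A) selection limits the values to the histone transcripts that it caught. Of 6 sperm genes 2 fell, spe-15 and spe-48, and 4 did not pass (2 adjusted over the list alone, median -0.18, adjusted p 0.616).

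Of 13 pharynx genes 12 rose after TOP-1 and DPY-27 depletion and 1 did not pass (12 adjusted over the list alone, adjusted p 0.000886), with myo-2, myo-1, myo-5 and tnc-2 (troponin C) between 5.47 and 6.26 in the authors' deposited table. Body wall muscle genes had 2 of 19 higher, unc-27 and mlc-2, both on the X, and 17 not passing (1 adjusted over the list alone, median 0.28, adjusted p 0.0459). Their autosomal members alone had a median of -0.01, and the adjusted p was 0.195 once the X or autosomal median was subtracted. Intestine genes had 5 of 17 higher, 1 lower and 11 not passing (5 and 1 adjusted over the list alone, median 0.55, adjusted p 0.0108, but 0.111 by cameraPR at 0.01), with pept-1 at 3.48 ± 0.40 and cpr-1, a cathepsin B-like protease gene, at 2.23 ± 0.46 in the authors' deposited table. Neuropeptide genes had 43 of 96 higher, 20 lower and 33 not passing (44 and 23 adjusted over the list alone, median 0.61, adjusted p 0.000886, but 0.1195 by cameraPR at 0.05), while the autosomal members alone had a median of 0.12. Among them nlp-71 was in the authors' deposited table at 5.64 ± 0.45 and flp-32 at 4.98 ± 0.39. Neuron genes had 4 of 23 higher, 10 lower and 9 not passing (4 and 10 adjusted over the list alone, median -0.42, adjusted p 0.174), with unc-104, the kinesin of synaptic vesicles, at -2.52 ± 0.38 in the authors' deposited table. The anterior markers outside the pharynx had a median of 4.70 with 5 of 6 higher, and the posterior markers -2.06 with 5 of 6 lower. Of 13 anterior markers found only those 6 had a mean of at least 10.

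Moulting genes had 15 of 24 lower, 1 higher and 8 not passing after TOP-1 and DPY-27 depletion (17 and 1 adjusted over the list alone, median -1.35, adjusted p 0.000886). The authors' deposited table had mlt-11, a protease inhibitor gene, at -4.13 ± 0.51, lin-42, related to the clock gene period, at -2.38 ± 0.40 and the transcription factor genes bed-3 and blmp-1 at -2.34 ± 0.37 and -1.99 ± 0.36. Cuticle collagens fell in 39 cases and rose in 16, with 67 not passing (41 and 16 adjusted over the list alone, median -0.69, adjusted p 0.000886, but 0.279 by cameraPR at 0.05), with col-172 at -3.93 ± 0.32 and col-96 at 6.25 ± 0.44 in the authors' deposited table. Hedgehog-related genes fell in 13 of 40 cases and rose in 4, with 23 not passing (13 and 4 adjusted over the list alone, median -0.59, adjusted p 0.00482, but 0.154 by cameraPR at 0.05), led by grl-10, grl-5, grl-16 and grl-2 between -3.07 and -2.08 in the authors' deposited table. Hypodermis genes had che-14 and lin-26 lower of 10, at -3.12 ± 0.38 and -1.57 ± 0.32 in the authors' deposited table (2 adjusted over the list alone, median -0.30, adjusted p 0.615). For the moulting, collagen and hedgehog-related lists, a phase of the moulting cycle other than that of the control was not tested.

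Innate immune effectors rose in 9 of 19 cases with 10 not passing (10 adjusted over the list alone, median 0.87, adjusted p 0.00482), with the lysozyme genes lys-7, ilys-3, lys-8 and lys-1 between 2.08 and 4.75 in the authors' deposited table. UDP-glucuronosyltransferases had 15 of 60 higher, 15 lower and 30 not passing (16 and 15 adjusted over the list alone, median 0.32, adjusted p 0.0439, but 0.0818 over genes with a mean of at least 100 and 0.821 by cameraPR at 0.01). Glutathione S-transferases had 12 of 40 higher, 3 lower and 25 not passing (13 and 3 adjusted over the list alone, median 0.44, adjusted p 0.0936), with gst-14, gst-12 and gst-24 at 4.82 ± 0.69, 3.37 ± 0.40 and 2.71 ± 0.38 in the authors' deposited table. Cytochrome P450s had 11 of 64 higher, 12 lower and 41 not passing (11 and 13 adjusted over the list alone, adjusted p 0.584), with a median of 0.21 and a mean of -0.02. Of 20 pals genes 6 rose and 14 did not pass (6 adjusted over the list alone, median 0.54, adjusted p 0.462), with pals-37 at 2.00 ± 0.50 in the authors' deposited table. Heat shock genes had 3 of 12 lower, 1 higher and 8 not passing (3 and 1 adjusted over the list alone, median -0.72, adjusted p 0.0571). Of 12 ER unfolded protein response genes hsp-4 and dnj-27 fell (2 adjusted over the list alone, median -0.50, adjusted p 0.18), and none of 7 mitochondrial unfolded protein response genes passed the test (0 adjusted over the list alone, median 0.01, adjusted p 0.653). Of 77 ribosomal protein genes rpl-11.1 rose and 76 did not pass (1 adjusted over the list alone, median -0.22, adjusted p 0.598). Of 24 oxidative phosphorylation genes 3 rose, sdha-1, gas-1 and ucr-2.1, all on the X, and 21 did not pass (1 adjusted over the list alone, median 0.15, adjusted p 0.0868). Of 16 fatty acid metabolism genes fat-5 fell and 15 did not pass (1 adjusted over the list alone, median 0.12, adjusted p 0.44). Of the 13 called lists 7 kept an adjusted p under 0.05 in limma's cameraPR with a preset correlation of 0.01. With one of 0.05, 4 kept an adjusted p under 0.05, namely pharynx, germline, innate immune effectors and moulting genes, and the lost calls had adjusted p from 0.119 (neuropeptides) to 0.901 (UDP-glucuronosyltransferases).

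Of the vitellogenin list, the yolk proteins, fewer than 3 members were measured, and vit-1 was at 4.51 ± 1.24 and 4.68 ± 1.21 in the authors' deposited tables for the TOP-2 and DPY-27 and the TOP-1 and DPY-27 depletion. The lists of mitochondrially encoded genes and ribosomal RNA genes likewise had fewer than 3 measured members and were not tested.

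Fold changes after TOP-1 and DPY-27 depletion fell with gene span. Spearman's rho was -0.27 over 10884 autosomal genes and Pearson's r -0.23 (permutation p 1e-05 for each, the smallest the permutations can give, adjusted p 2e-05 for rho). On the X both were negative too, rho -0.21 and r -0.23 over 2053 genes (permutation p 1e-05, adjusted p 2e-05). The autosomal median went from 0.05 for genes under 1 kb to -0.46 for 5 to 10 kb and -0.94 for genes over 20 kb, of which 90 of 168 fell and 1 rose. X genes had medians from 1.39 under 1 kb to 0.09 over 20 kb.

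**Figure D2:**
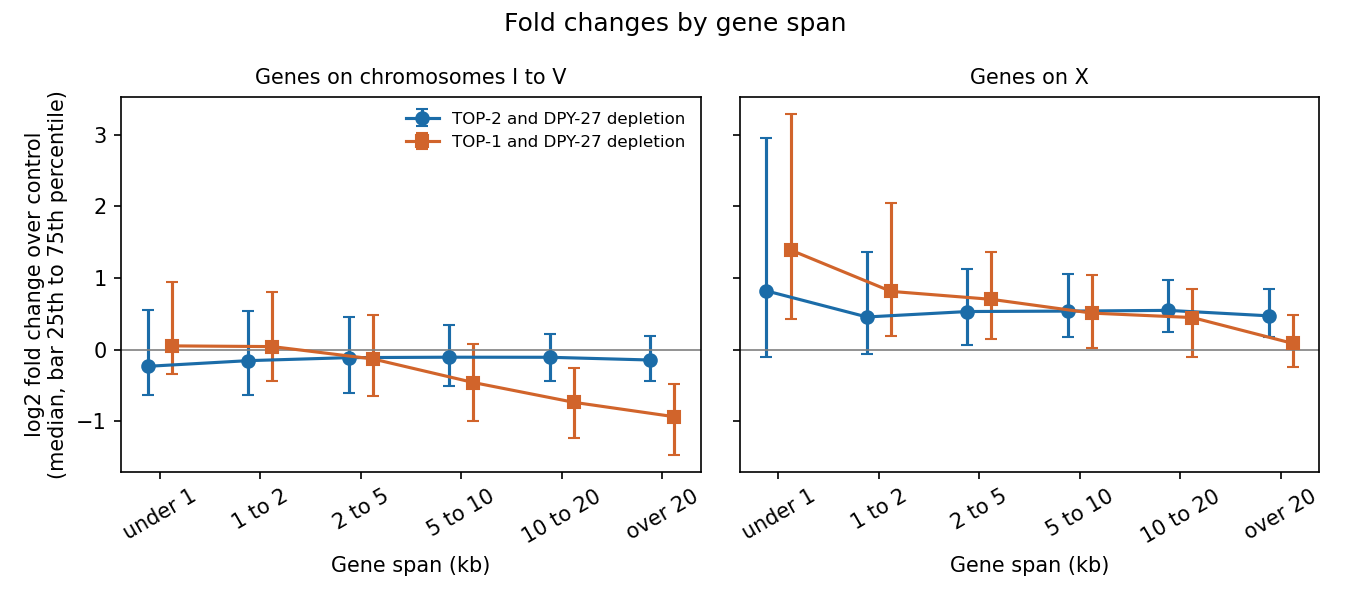
Median log2 fold change over control by gene span in kb, for autosomal genes and X genes, with bars from the 25th to the 75th percentile of genes. After TOP-1 and DPY-27 depletion the autosomal medians go from 0.05 to -0.94, and after TOP-2 and DPY-27 depletion they stay between -0.23 and -0.11.

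The depletions were compared with each other by the difference of their fold changes, in which the common control cancels. Genes with long spans stood higher after TOP-2 and DPY-27 depletion than after TOP-1 and DPY-27 depletion, and the X shift was smaller by 0.16 on the log2 scale. Moulting genes (median difference 0.71) stood higher after TOP-2 and DPY-27 depletion, and glutathione S-transferases (-1.01), innate immune effectors (-0.68) and oxidative phosphorylation (-0.51) stood lower. Whether the strains differed in their phase of the moulting cycle was not tested. With the SEs taken as independent, 15 of 13027 single genes passed, 9 higher and 6 lower after TOP-2 and DPY-27 depletion. That overstates the SE, and with a share of 0.5 of the mean squared SE taken as due to the common control 337 passed, 236 higher and 101 lower.

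The median difference was -0.09 over 2067 X genes and 0.07 over 10960 autosomal genes, so that the X shift differed by -0.16, with random lists between -0.05 and 0.05 (p 0.0002, the smallest the random lists can give). The rank correlation of the difference with gene span was 0.46 over 10692 autosomal genes and 0.37 over 2011 X genes (permutation p 1e-05 for each, the smallest the permutations can give), with Pearson's r of 0.43 and 0.33. Autosomal medians of the difference went from -0.23 under 1 kb to 0.79 over 20 kb. Against random lists matched on expression and span, chosen after seeing the data, whose median differences lay between 0.02 and 0.11, the median of X genes differed by -0.16.

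Named by the rule, the differing genes that were higher after TOP-2 and DPY-27 depletion were suex-1 (difference 3.04 ± 0.73, adjusted p 0.0382), dpy-1, needed for body shape (2.94 ± 0.72, adjusted p 0.0419), the astacin protease gene nas-38 (2.70 ± 0.61, adjusted p 0.0242), trp-4 (2.44 ± 0.54, adjusted p 0.0161) and hum-7, an unconventional myosin gene (2.39 ± 0.52, adjusted p 0.0114). The collagen gene col-101 was lower (-4.0 ± 0.70, adjusted p 0.000175). In the authors' deposited tables nas-38 was at 2.5 ± 0.45 after TOP-2 and DPY-27 depletion and at -0.20 ± 0.42 after TOP-1 and DPY-27 depletion, and col-101 at -2.34 ± 0.44 and 1.66 ± 0.55. Of the other called genes, named after their values were seen, tmem-120, sorb-1 and snf-6 were higher and nhx-6, a sodium/proton exchanger gene, was lower (difference -5.70 ± 1.08). A further 5 called genes, 4 lower and 1 higher, have no symbol and were skipped by the rule. These genes come from the count that takes the SEs as independent. With a share of 0.333 of the mean squared SE taken as the control's, those higher were 66 and those lower 38.

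Of the 31 lists 12 differed between the depletions, and these also passed when random lists were matched on gene span. By cameraPR, added after seeing the data, 11 of them passed at a preset correlation of 0.01 and 4 at 0.05, namely moulting genes, glutathione S-transferases, innate immune effectors and oxidative phosphorylation. Hedgehog-related genes were at 0.234 and 0.446. Lower after TOP-2 and DPY-27 depletion were glutathione S-transferases (median difference -1.01, adjusted p 0.000886), innate immune effectors (-0.68, adjusted p 0.000886), oxidative phosphorylation (-0.51, adjusted p 0.00207), pals genes (-0.46, adjusted p 0.0113), intestine (-0.41, adjusted p 0.0113), cytochrome P450s (-0.40, adjusted p 0.000886), neuropeptides (-0.33, adjusted p 0.000886) and UDP-glucuronosyltransferases (-0.29, adjusted p 0.000886). Higher were moulting genes (0.71, adjusted p 0.000886), germline (0.52, adjusted p 0.00155), hedgehog-related genes (0.48, adjusted p 0.000886) and DNA replication and mitosis (0.40, adjusted p 0.017). Few of their members passed singly, even with a share of 0.5 of the mean squared SE taken as the control's: 5 glutathione S-transferases, 2 immune effectors, 2 cytochrome P450s and 1 UDP-glucuronosyltransferase lower, and 3 moulting genes higher. Against the direction of their lists went 2 neuropeptide genes, higher, and 1 hedgehog-related gene, lower, and the pals, germline, intestine, oxidative phosphorylation and DNA replication lists had 0 members passing. Over genes with a mean of at least 100 the pals and germline calls were lost, with adjusted p 0.12 and 0.157. The difference of the pharynx list was 0.31 (adjusted p 0.141), that of the condensin DC list 0.38 (adjusted p 0.122) and that of histone genes 0.28 (adjusted p 0.0822).

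The calls of the depletions overlapped. Among 14646 genes tested in both, 1706 rose in both, against 357.6 for independent lists, 809 fell in both, against 145.3, and 4 went in opposite directions. Across genes Pearson's r of the fold changes was 0.91 and Spearman's rho 0.84. Simulated unchanged groups against a common control gave r of 0.50 and 0 common calls, with a share of 0.5 of the variance taken as the control's. The covariance was 2.74 against 0.265 simulated, a difference of 2.47. The simulation draws only random error of the control, so an offset of the control in stage or tissue content is absent from it. The control could not be split without values per sample. Part of the excess over independent lists and over the simulation may therefore come from the common control, and genes are not independent replicates.

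**Figure D3:**
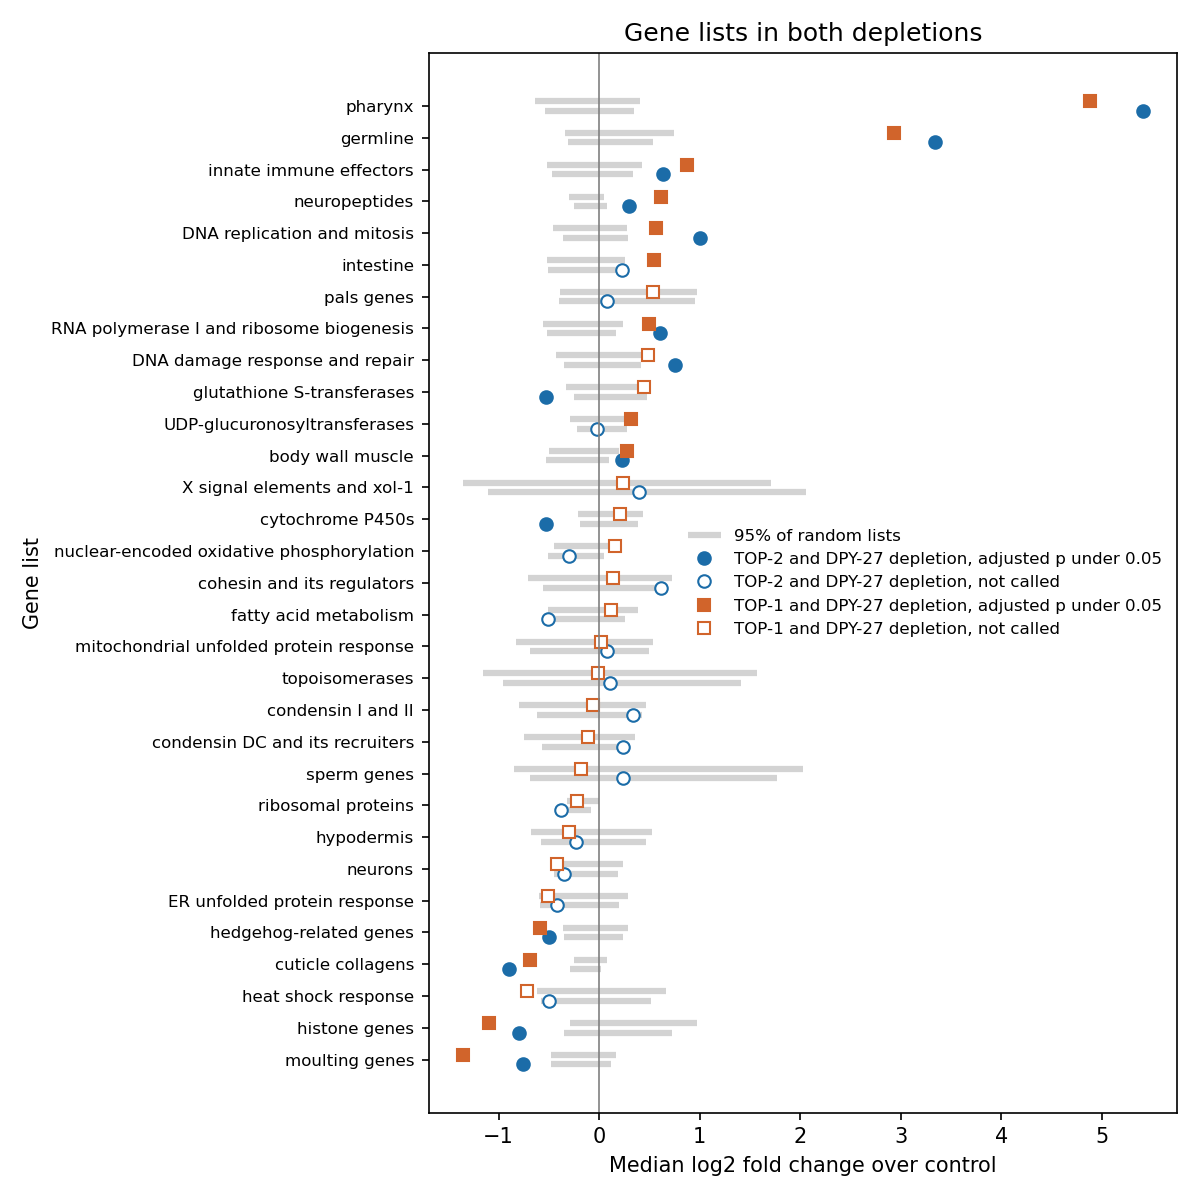
Median log2 fold change over control of the 31 tested gene lists after each depletion, with filled points for lists at an adjusted p under 0.05, open points for the others, and grey bars for 95% of random lists matched on expression. Pharynx and germline lie farthest to the right, at 5.41 and 3.34 after TOP-2 and DPY-27 depletion and at 4.88 and 2.93 after TOP-1 and DPY-27 depletion.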

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

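Among the tests here, those of the lists in the difference between the depletions, cameraPR on it, of matching on gene span and of genes on the X or of high or low expression only were chosen after the result was seen. All results in this part were singled out because a test of the difference itself found the depletions to differ. The X shift was smaller after TOP-2 and DPY-27 depletion than after TOP-1 and DPY-27 depletion, by -0.158 on the log2 scale. Single genes differed in 15 cases with the SEs taken as independent, which overstates the SE, and in 337 with a share of 0.5 of the mean squared SE taken as due to the common control. The median difference (TOP-2 and DPY-27 minus TOP-1 and DPY-27) was -1.006 for glutathione S-transferases, -0.683 for innate immune effectors, -0.510 for oxidative phosphorylation and -0.460 for pals genes. It was -0.411 for intestine genes, -0.396 for cytochrome P450s, -0.331 for neuropeptides and -0.292 for UDP-glucuronosyltransferases. On the other side it was 0.714 for moulting genes, 0.517 for germline genes, 0.481 for hedgehog-related genes and 0.398 for DNA replication and mitosis. By cameraPR at a preset correlation of 0.05 only glutathione S-transferases, immune effectors, oxidative phosphorylation and moulting genes of these 12 lists passed. For moulting and hedgehog-related genes, a difference between the strains in phase of the moulting cycle was not tested and stays open.

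Long genes were lower relative to short ones after TOP-1 and DPY-27 depletion than after TOP-2 and DPY-27 depletion, with a rank correlation of the difference with gene span of 0.464 on autosomes and 0.370 on the X. A bias with transcript length in the libraries would follow exonic length, but the rank partial correlation with span at fixed exonic length was 0.257 and that with exonic length at fixed span 0.022, which argues against it. Less neuronal RNA after TOP-1 and DPY-27 depletion would lower the short neuropeptide genes too, but their median difference was -0.331 (random lists matched on span -0.17), while panels of ciliated and head neuron genes, which are longer, were at 0.60 and 0.47 (random lists 0.36 and 0.16). A relation confined to the X or to an expression class is argued against by the lowest rank correlation among X, autosomes and genes of low, middle and high expression, 0.304. Loss of TOP-1 rather than TOP-2 may act on the transcription of long genes, a hypothesis found and examined on the same tables, and a change in some types of neuron and differences between the strains other than the tags stay open.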

How the results depend on the processing

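No paired analysis was possible because the tables hold no values per sample, and for the same reason leaving out each replicate, a replicate block and splitting the control could not be done. Chosen after seeing the data were leaving out genes by their value in the other depletion's table, centring the difference, testing lists in the difference, with cameraPR too, and matching lists on gene span. The X shift kept its sign and side of the threshold in all 28 alternatives (0.427 to 0.776 after TOP-2 and DPY-27 depletion and 0.626 to 0.912 after TOP-1 and DPY-27 depletion), the X share of calls in all 8, the difference in X shift in all 3 and the position along X in both. The lowest shifts, 0.427 and 0.626, came from leaving out genes by their value in the other depletion's table, which by itself tends to lower the shift. Counts of changed genes stayed within 1.5 times in 10 alternatives. With Benjamini-Yekutieli adjustment they were 1954 after TOP-2 and DPY-27 depletion and 2773 after TOP-1 and DPY-27 depletion, and without genes called the same way after both depletions they were by construction fewer, at 708 and 1927. Genes differing between the depletions numbered 337 with a share of 0.5 of the mean squared SE taken as common control, 66 higher and 38 lower (1.0e+02 in all) with a share of 0.333, and 3 at an adjusted p under 0.01, and stayed within 1.5 times in 2 alternatives. The covariance above the simulated one was 2.559 with a share of 0.333 of the variance as the control's. The relation with span after TOP-1 and DPY-27 depletion kept its sign and call in all 8 alternatives. After TOP-2 and DPY-27 depletion the autosomal rho turned to -0.011 with a floor of 1 and passed the threshold at 0.089 with a floor of 100, 0.097 for exonic length and 0.067 given mean expression. On the X rho passed at -0.051 with a floor of 1 and turned to 0.078 with a floor of 100, 0.031 for exonic length and 0.041 given mean expression. For gene lists against the control, 241 alternatives kept direction and call, 40 lost the call, 7 gained it and 21 turned direction relative to random lists. In the difference these numbers were 123, 11, 11 and 9. All values that follow are adjusted p, with limma for cameraPR. With cameraPR at a preset correlation of 0.01 the calls lost after TOP-2 and DPY-27 depletion were histone genes (0.0774), DNA damage (0.071), glutathione S-transferases (0.0624), immune effectors (0.15), moulting (0.0774), hedgehog-related (0.223) and body wall muscle (0.559). Gained were cohesin (0.0271), heat shock (0.0255) and ribosomal proteins (0.00629), and the mitochondrial unfolded protein response (0.889) and pals genes (0.904) turned. After TOP-1 and DPY-27 depletion it lost histone genes (0.0704), UDP-glucuronosyltransferases (0.821), body wall muscle (0.508), intestine (0.111), ribosome biogenesis (0.381) and DNA replication (0.137). Condensin DC (0.691), cytochrome P450s (0.45) and fatty acid metabolism (0.787) turned. At a correlation of 0.05 the TOP-2 and DPY-27 depletion lost histone genes (0.291), DNA damage (0.279), cytochrome P450s (0.257), glutathione S-transferases (0.288), immune effectors (0.34), collagens (0.154), moulting (0.285), hedgehog-related (0.486), body wall muscle (0.693), neuropeptides (0.327), ribosome biogenesis (0.154) and DNA replication (0.0534). The mitochondrial unfolded protein response (0.903) and pals genes (0.927) turned. The TOP-1 and DPY-27 depletion then lost histone genes (0.285), UDP-glucuronosyltransferases (0.901), collagens (0.279), hedgehog-related (0.154), body wall muscle (0.693), intestine (0.288), neuropeptides (0.119), ribosome biogenesis (0.538) and DNA replication (0.346). Condensin DC (0.735), cytochrome P450s (0.693) and fatty acid metabolism (0.849) turned. In the difference cameraPR at 0.01 lost hedgehog-related genes (0.234), gained condensin I and II (0.02), cohesin (0.0256), heat shock (0.0418), ribosomal proteins (0.00403), ribosome biogenesis (0.0152) and fatty acid metabolism (0.000996), and turned collagens (0.561) and body wall muscle (0.797). At 0.05 it lost cytochrome P450s (0.0515), UDP-glucuronosyltransferases (0.0951), pals genes (0.0779), hedgehog-related (0.446), germline (0.0951), intestine (0.13), neuropeptides (0.0779) and DNA replication (0.0779), gained fatty acid metabolism (0.0175), and turned collagens (0.789) and body wall muscle (0.853). Subtracting the X or autosomal median ended the body wall muscle calls (0.0682 after TOP-2 and DPY-27 and 0.195 after TOP-1 and DPY-27 depletion). It also turned X signal elements (0.763 and 0.537), UDP-glucuronosyltransferases (0.962) and pals genes (0.962) in the former, and ribosomal proteins (0.822) in the latter, where oxidative phosphorylation was gained (0.00763). Over genes with a mean of at least 100, neuropeptides were lost after TOP-2 and DPY-27 depletion (0.66), and heat shock (0.528), pals (0.201) and sperm genes (0.614) turned. After TOP-1 and DPY-27 depletion histone genes (0.26), UDP-glucuronosyltransferases (0.0818) and body wall muscle (0.0502) were lost, pals (0.0356) and neurons (0.0077) gained, and topoisomerases turned (0.975). In the difference pals (0.12) and germline (0.157) were lost, collagens (0.000857) and sperm genes (0.024) gained, and heat shock turned (0.998). With lists matched on expression and span, ribosomal proteins (0.203) and oxidative phosphorylation (0.584) turned after TOP-2 and DPY-27 depletion, and heat shock was gained after TOP-1 and DPY-27 depletion (0.0473). In the difference histone genes (0.00062) and collagens (0.00062) were gained, and topoisomerases (0.719), X signal elements (0.805), hypodermis (0.719) and ribosomal proteins (0.00225) turned. A floor of 100 tests fewer genes, and otherwise the cause was not tested. With the deposited means and SEs, simulated changes of 1 on the log2 scale were called in 10% of cases for TOP-2 and DPY-27 and 18% for TOP-1 and DPY-27 depletion, and the part of depth in this was not tested. Only 50 genes of each size were changed there, far fewer than were called against the control, so these percentages may understate recovery in the deposited tables.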

Other observations

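In this part the tests of X derepression, of the moulting cycle, of a minority of X genes, of ciliated neurons and of head neurons were chosen only after the result was seen, as were all panels and genes named here. No list of genes that pattern the body axis was tested, and the single genes that follow show no more than their own values. The Hox genes lin-39, of the midbody, and ceh-13, of the anterior, were in the authors' deposited tables for TOP-2 and DPY-27 depletion and TOP-1 and DPY-27 depletion at 2.16 and 2.04 and at 2.78 and 3.0. The posterior Hox genes php-3, nob-1 and egl-5 were at -2.25, -2.33 and -2.24 and at -2.77, -2.69 and -2.81 in the authors' deposited tables. The Wnt genes of the tail, egl-20 and lin-44, were at -2.41 and -2.57 after TOP-2 and DPY-27 depletion and at -3.91 and -3.37 after TOP-1 and DPY-27 depletion in the authors' deposited tables. A panel of 12 tail genes had medians of -1.39 and -1.52, with 8 lower and 1 higher in each. The EGF gene lin-3 was at 4.70 and 4.39 in the authors' deposited tables, and the FGF gene egl-17 at 4.00 and 3.61. A panel of vulva and somatic gonad genes had medians of 0.70 and 0.48 (autosomal members alone -0.06 and -0.37) and coelomocyte and excretory genes 1.64 and 0.75 (autosomal members alone 0.01 and 0.11). Head glia genes had medians of -0.11 and -0.36 and ventral cord motor neuron genes 0.54 and 0.24. The abu and pqn genes, many of them of the pharyngeal cuticle, had medians of 5.01 and 3.44, and 9 and 8 of 11 were higher.

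Single genes of sensory neurons were looked at too, with no test of any neuron type. Of the BAG neurons, flp-17 was at 5.68 and 6.05 and gcy-33 at -1.45 and -1.68 in the authors' deposited tables. Of the AFD neurons, gcy-23 was at 5.76 and 4.88, gcy-8 at 3.82 and 1.98 and ttx-1 at -0.24 and -1.63 in the authors' deposited tables, where gcy-8 did not pass after TOP-1 and DPY-27 depletion and ttx-1 not after TOP-2 and DPY-27 depletion. The hormone genes daf-7 and daf-28 were at 6.07 and 5.32 after TOP-2 and DPY-27 depletion and at 5.70 and 5.66 after TOP-1 and DPY-27 depletion in the authors' deposited tables. The body wall myosin genes unc-54 and myo-3 were between -0.01 and 0.28 there.

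Pharyngeal transcripts were far higher in both depletions than in the control, and a technical candidate is that the control libraries held less RNA of anterior tissue. Anterior markers outside the pharynx, predicted to be high, had medians of 5.492 and 4.696, and posterior markers, predicted to be low, -1.713 and -2.064. Only 7 and 6 of 13 anterior markers found had a mean of at least 10. That floor keeps genes very low in the control only where they are high after the depletion. The anterior medians are therefore biased upward and weigh little here, while all 6 posterior markers found were measured. A lack of all head tissue alike is argued against by a ciliated neuron panel at -0.421 and -0.948 and a head neuron panel at -0.114 (7 higher and 7 lower of 30) and -0.682 (7 higher and 10 lower), and derepression of X genes by autosomal pharynx genes at 5.412 and 4.881. A different phase of the moulting cycle stays open, since the contractile genes examined for it, at 6.046 and 5.599, are members of the pharynx list itself. A control short of some anterior and inner tissues and richer in posterior ones may therefore lie behind part of the tissue lists, as a hypothesis that bears on comparisons with the control and not on the differences between the depletions, and an effect of the depletions or strains on these tissues stays open, since each comparison uses the same control.

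X genes stood above autosomal genes in both depletions, as they would if loss of DPY-27 lifted the repression of the X. A minority of X genes from tissues that the control lacks would leave the lower part of the distribution in place, but the 25th percentile of X genes lay above that of autosomal genes by 0.670 and 0.807. Longer X genes or other expression levels are argued against by shifts of 0.670 and 0.827, above every random list matched on expression and span (highest 0.08 and 0.05). Both strains lost DPY-27 together with a topoisomerase, so the share of each in the shift may differ in ways these comparisons do not separate. The difference of the shifts, -0.162 against random lists matched on expression and span, sets the strains against each other only. It gives no share of DPY-27, and how far DPY-27 was lost in each strain cannot be told from these values.

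With 2 control and 2 depletion libraries assumed, the control means implied by both tables kept a constant ratio, with a standard deviation of 0.0042 on the log2 scale over 7193 genes, against 0.0441 to 0.112 for other numbers of control libraries, so the same control values enter both tables.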
